A study of Mus musculus with 2 samples.

How the data were processed

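Lung tissue of Bclaf1 knockout and wild-type mice was compared on 2 two-colour arrays of spotted mouse cDNA clones. Per the labels' protocols, total RNA was extracted with TRI reagent, checked on a bioanalyzer, reverse transcribed with Superscript II, labelled with Cy5 (wild type) or Cy3 (knockout) and scanned on an Agilent G2505B scanner. Both arrays had the same dye orientation. The labels number the RNA pairs but do not say that they came from separate animals, so p-values measure only the spread between these 2 arrays, which may be technical.

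The deposited value table gives 1 log2 ratio per clone and array. The background correction, normalization and software are not given in the sources used here; the base was read from the values, since the mean of the arrays had a slope of 0.974 on the log2 of the authors' fold change (Pearson r 0.990). The medians lay near 0, so the arrays were taken as centred by the authors, while the direction of the ratio stays unknown. Per the file headers, the authors' deposited tables of up-regulated and down-regulated clones give a linear fold change and a p-value per clone. The test behind these p-values, whether they were adjusted and how clones were selected are not given in the sources used here. Signal intensities and spot flags were not used here, so a filter on dim spots was not run.

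The value table held 22656 clones and 3 control features, which were left out. Values were missing for 9 clones on array 1 and 115 on array 2, and the 22532 clones with both values were tested as deposited. Gene names came from the authors' tables and so cover listed clones only. Of the 3509 listed clones, 2285 were named through their gene ID in a RefSeq gene table (assembly GRCm38.p6, used for names alone), 7 through a transcript accession, 128 by a current and 44 by an older symbol, and 58 kept the file's symbol. For 75 clones the symbol and the gene ID named different genes, and these were left unnamed, as were 912 clones without a symbol. The rule for the 75 clones was set after the gene list results with these clones under their gene ID had been seen, and results that moved with it are given both ways. In all, 2522 clones carried 2261 gene names. No coordinates are given, since the sources used here name no genome build.

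Each clone's mean log2 ratio over the arrays was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 arrays, 1 residual degree of freedom remains per clone before moderation. Clones past 1.5-fold on both arrays were counted by direction, with no p-value. Gene lists were tested with limma's camera on the mean ratio of the clones of a gene, with a preset correlation of 0.01, where at least 5 genes were measured, adjusted over the 9 lists tested. The list median was also placed among 10000 random lists of the same size drawn from the named genes.

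The tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The lists were alveolar type II, alveolar type I, airway, smooth muscle, extracellular matrix, endothelial, red cell, leukocyte, lymphocyte and thymus, heart and striated muscle, liver, cell cycle, apoptosis and p53 response, RNA splicing, lung developmental signalling, oxidative phosphorylation, hypoxia and glycolysis, immediate early and stress response, sex-linked, and cytosolic ribosomal protein. The rule named Bclaf1, 10 genes per side, the 3 members of each list with the largest absolute mean and the sex-linked genes. Where fewer than 10 genes per side passed the test, the places were filled by genes with the same sign on both arrays, ranked by the smaller absolute log2 ratio, leaving out clone-type names. The values of 1 gene that the rule would name are not reported here.

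The alternatives were centring each array on its median, scaling to the same median absolute deviation, quantile normalization, robust eBayes, an ordinary one-sample test, averaging the clones of a gene, clones measured on at least 1 array, other thresholds, an estimated correlation, fry, every clone as a list member, leaving ribosomal proteins out of the background, and each array alone. Added later were the subtraction of block medians, Fisher's exact test, leaving out genes whose clones disagree, and the other naming of the 75 clones, alone and with block medians subtracted. A block is 384 consecutive clone numbers; in blocks 1 to 40, 99.3% of the readable well positions in the authors' tables carry the block's number as plate number. In blocks 41 to 59 the plate numbers start anew and blocks span neighbouring plates, with 64.8% of readable positions on the commonest plate of their block. In all, 214 positions that had turned into plain numbers were not used.

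The scripts were tested on simulated data. The limma simulations gave 200 clones a change of the same size at once, so their rates need not hold where fewer clones change. With 200 of 22532 clones changed and the spread of the real arrays, limma recovered 0% at a log2 change of 0.4, 0% at 1, 79% at 2 and 99.5% at 4, with 0, 0, 13 and 21 false calls. Camera called a list of 20 genes shifted by 0.3 in 100% of 100 simulations and an unshifted list in 2%. These simulated genes were drawn around 0, independently of each other and between arrays. The named genes were selected by the authors on these arrays and share block offsets, so these rates need not hold for them. Permutations, Fisher's exact tests and plots used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.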

Results

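The study compared lung tissue of mice that lacked Bclaf1 with lung tissue of wild-type mice. Bclaf1 encodes a nuclear protein that binds the apoptosis regulator Bcl2 and takes part in messenger RNA processing. RNA from 1 wild-type and 1 knockout lung sample was hybridised together on each of 2 spotted cDNA arrays, so each array gave 1 ratio of the genotypes per clone. The series text places the tissue at postnatal day 1, whereas the sample titles place it at embryonic day 19, and the stage was left open here. The value table held 22656 mouse cDNA clones, of which 22532 had a value on both arrays. The median log2 ratio was 0.0071 on array 1 and 0.0042 on array 2, with an SD across clones of 0.299 and 0.430. Only 2 arrays were made, and this number limits the precision of every value below.

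On both arrays the wild-type sample carried the dye Cy5 and the knockout sample the dye Cy3, so dye and genotype cannot be told apart in any ratio. The value table does not state which channel was the numerator. Read as Cy5 over Cy3, a positive ratio means a higher level in wild-type lung; read from the names of the authors' lists, it means a higher level in knockout lung. The values did not settle this, so ratios are given here as lying on the positive or the negative side, where the positive side holds the authors' up-regulated list. The other reading would turn every sign together.

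Bclaf1 itself, the targeted gene on chromosome 10, was represented by 1 named clone. Its log2 ratio was 0.40 on array 1 and 0.41 on array 2, a mean of 0.41 ± 0.0083 (SD, n = 2 arrays) and a 1.32-fold difference between the channels. The clone was in the up-regulated list of the authors' deposited table. With Cy5 as numerator the knockout sample had the lower Bclaf1 signal; with knockout as numerator it had the higher signal, which goes against the label. Where this clone lies relative to the deleted part of the gene is not given in the sources used here, so it does not check the labels. The limma adjusted p for this clone was 0.349.

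The comparison of knockout with wild-type lung asked which genes differ between them. For each side, 10 genes were taken by the smaller of their ratios on the arrays, and these are values, not calls, since no clone passed the test. The 10 on the positive side differed 3.08-fold to 7.12-fold. Brip1, a helicase of DNA repair that binds Brca1, had a mean log2 ratio of 2.83 ± 0.49 (SD, n = 2), and Xist, the RNA that coats the inactive X chromosome, had 2.42 ± 0.38. Others were Noc2l, a repressor of histone acetylation (2.46 ± 0.47), Sin3a, the scaffold of a histone deacetylase complex (1.70 ± 0.064), Ss18, a subunit of a chromatin remodelling complex (1.89 ± 0.36), and Ahctf1, which is needed for nuclear pore assembly (1.75 ± 0.38). The rest were Oxsm, an enzyme of mitochondrial fatty acid synthesis (2.26 ± 0.16), Slc25a40, a mitochondrial carrier (2.09 ± 0.43), Stard4, a cholesterol transfer protein (1.63 ± 0.028), and Tenm3, a teneurin of the cell surface (1.62 ± 0.045).

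The 10 genes on the negative side differed 1.63-fold to 3.13-fold. Tulp3, which carries receptors into cilia, had the widest spread, with -0.93 on array 1 and -2.36 on array 2. Wipi1, a protein of autophagosome formation, had -1.03 on both arrays. Mean log2 ratios were -1.10 ± 0.46 for Pcsk1n, an inhibitor of a prohormone convertase, -1.04 ± 0.21 for Aff3, a nuclear transcription factor, -0.95 ± 0.23 for Zfand3, a zinc finger protein, and -0.99 ± 0.31 for Pdcd2l. They were -0.92 ± 0.25 for Mrpl19, a mitochondrial ribosomal protein, -0.84 ± 0.21 for Hnrnpdl, an RNA-binding protein, -0.90 ± 0.35 for Entpd4, a nucleotidase of the Golgi apparatus, and -0.71 ± 0.011 for Dcaf7, a WD-repeat scaffold protein (SD, n = 2 arrays each). Each of these values, on both sides, is that of 1 chosen clone. The authors had selected all named clones on these arrays, and the ranking used the smaller ratio. Both can favour clones whose arrays agree, so the SDs given here and below may be too small. Averaged over all named clones of the gene, the mean log2 ratio was 0.51 for Tenm3, -0.55 for Aff3, -0.27 for Hnrnpdl and 0.048 for Dcaf7.

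**Figure D1:**
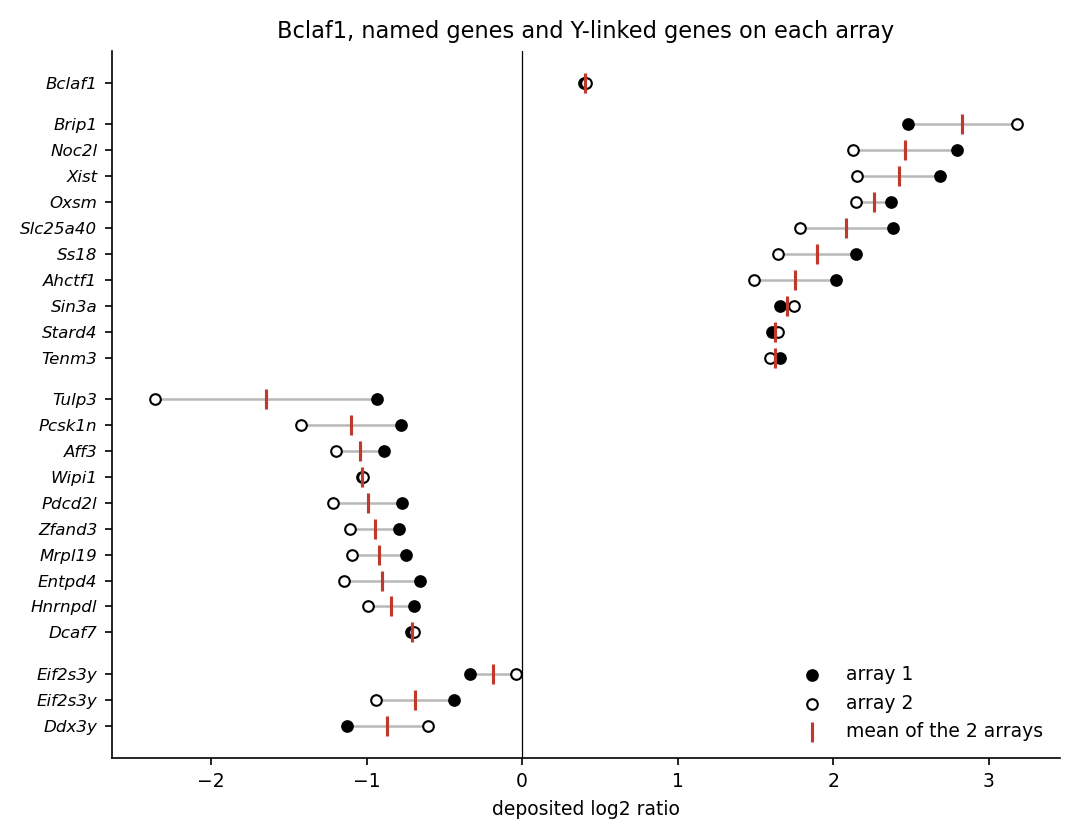
Log2 ratios of Bclaf1, the 10 named genes of each side and the Y-linked genes (rows), with array 1 as filled circles, array 2 as open circles and their mean as a red bar. Bclaf1 lies at 0.40 and 0.41; array 1 and array 2 lie farthest apart for Tulp3, at -0.93 and -2.36.

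Sex-linked genes, of which 3 were measured, were too few for a test and are given as values. Xist lay at 2.69 on array 1 and 2.15 on array 2, whereas Ddx3y, a Y-linked RNA helicase, lay at -1.12 and -0.61. Eif2s3y, a Y-linked translation initiation factor subunit, had -0.44 and -0.94 for 1 clone and -0.34 and -0.04 for the other. All 8 values thus had Xist on the positive side and the Y-linked genes on the negative side. A further clone, tied to Xist by gene ID and to another gene by symbol, lay at 0.64 and 0.37. The sexes of the animals are not given in the sources used here.

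In limma's test of the mean ratio against 0, 0 of 22532 clones had a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.349. At an unadjusted p under 0.05 there were 3138 clones, 1803 on the positive and 1335 on the negative side, where 1126.6 were to be expected by chance. The ordinary one-sample test also made 0 calls after adjustment, with 1861 clones at an unadjusted p under 0.05. With the median of each block of consecutive clone numbers subtracted, 45.0% of the clones at an unadjusted p under 0.05 were positive, against 57.5% as deposited. On simulated arrays of 22532 clones, 200 clones were given a change of the same size. Limma recovered 0% of changes of 1 on the log2 scale, 79% of changes of 2 and 99.5% of changes of 4. With fewer clones changed the adjustment is stricter, so these rates need not hold for the real arrays. There, Brip1, Noc2l, Xist and Oxsm had mean log2 ratios of 2.83, 2.46, 2.42 and 2.26, each with a limma adjusted p of 0.349.

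Past 1.5-fold on both arrays in the same direction were 114 clones on the positive and 70 on the negative side, beside 30 clones past 1.5-fold in opposite directions. Past 2-fold these counts were 36, 2 and 2, and the negative count was 6 with arrays brought to the same median absolute deviation and 10 after quantile normalization. The split between the sides depended on the scale of the arrays: past 1.5-fold, equal median absolute deviations gave 99 positive and 113 negative clones, and quantile normalization 107 and 146. Across clones the arrays correlated with a Pearson r of 0.357 and a Spearman rho of 0.482, and 69.6% of clones had the same sign on both; clones are not independent replicates, and a dye effect would be shared by both arrays.

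**Figure D2:**
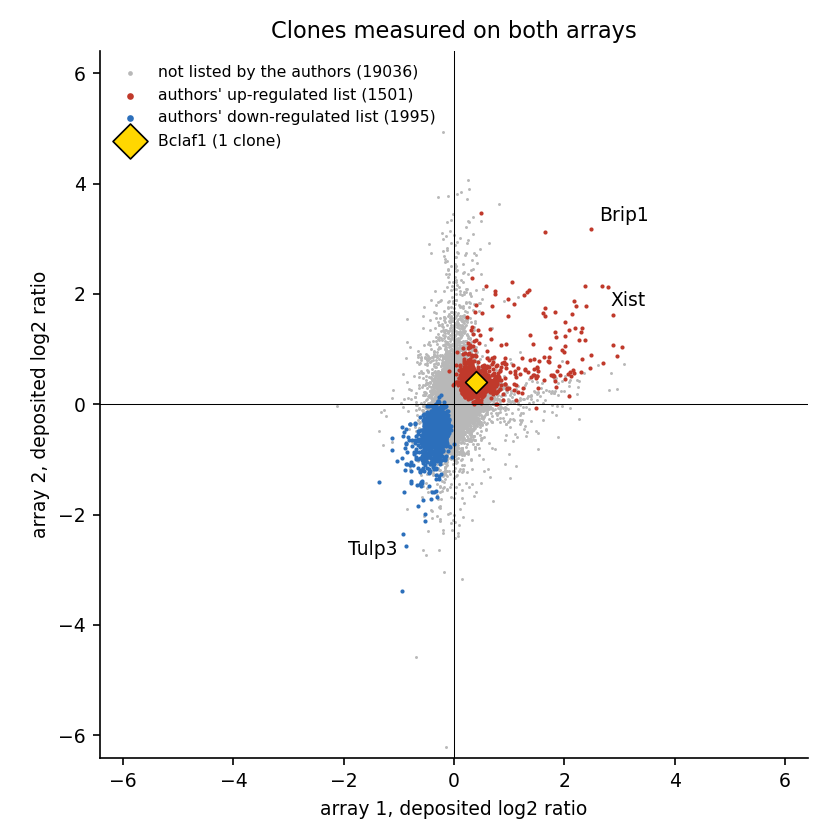
Deposited log2 ratio of each clone on array 1 (x axis) against array 2 (y axis), for the 22532 clones measured on both, with the authors' up-regulated clones in red, their down-regulated clones in blue, other clones in grey and Bclaf1 as a diamond. Of the listed clones, 1496 up-regulated and 1987 down-regulated lie where both arrays have the same sign, and many unlisted clones lie far from 0 on 1 array only.

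The authors' deposited tables list 1510 up-regulated and 1999 down-regulated clones, 15.5% of the clones on the array. Their fold changes ran from 1.13 to 15.96 in the up-regulated table (median 1.27) and from 0.27 to 0.90 in the down-regulated table (median 0.79), with p-values of 0.01 to 0.05. Of these, 204 up-regulated and 253 down-regulated clones reached 1.5-fold. Of the up-regulated clones measured on both arrays, 1496 of 1501 were positive on both, and of the down-regulated clones 1987 of 1995 were negative on both. The authors chose these clones on the same arrays, so this is not independent evidence of a direction. The largest fold changes in the authors' deposited table were those of P2ry10, a G-protein-coupled receptor of lymphoid cells (15.96), Lyn, a kinase of B cells and myeloid cells (9.62), and Cd96, a receptor of T and NK cells (9.09). Each of these 3 clones had a deposited value on 1 array only (log2 ratios 3.70, 2.88 and 2.80), so no replicate value is available. The listed fold changes are larger than these ratios give, so what they were computed from stays open. The authors nevertheless gave each a p of 0.02, and 13 listed clones in all had a value on 1 array only. What spread these p-values measure is not given in the sources used here. The 3 clones were picked out after their values were seen.

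Gene groups could be examined only among the genes that the authors' tables name, all of which the authors had already selected. This left 2253 genes measured on both arrays, 1092 positive and 1161 negative. A list could therefore differ only in how its members fell on the sides. Listed fold changes were at least 1.13 or at most 0.90, so a list median follows the side with more members and is no effect size. Medians of 0.28, -0.25 and 0.15 for splicing, smooth muscle and lung developmental signalling stood beside means of 0.069, -0.0064 and 0.019. For cell cycle and ribosomal genes the means were 0.25 and -0.24, near the medians. A count of members with a limma p adjusted over the list alone is not independent evidence either, since the authors had selected every member. Of the 2253 genes 1732 had an unadjusted limma p under 0.05, so many members of a list can pass by selection. Adjusted over all 2253 genes, 0 passed (lowest adjusted p 0.0521), and over all clones every count was 0.

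Cytosolic ribosomal proteins lay mostly on the negative side. Of 20 named genes, 17 were negative and 3 positive, with a median log2 ratio of -0.29, and 19 had the same sign on both arrays. Rplp1, of the ribosomal stalk, had -0.49 ± 0.20 and Rpl11, which can bind Mdm2, -0.39 ± 0.023 (SD, n = 2). Camera gave an adjusted p of 0.0192 over 9 lists, and the median lay at percentile 2.58 of random lists of the same size. The call was lost after quantile normalization (adjusted p = 0.0618). With an estimated correlation every tested list had a camera adjusted p of 0.853. That correlation rests on 1 residual degree of freedom, so this alternative had little power to call any list. Fry, which asks whether the genes move on balance to 1 side and does not compare them with other genes, gave an adjusted p of 0.105. Adjusted over the list alone, 16 of the 20 genes passed. The list leaves out 5 clones that the tables tie to a ribosomal protein by gene ID and to another gene by symbol; with them under their gene ID the adjusted p was 0.0407. With block medians subtracted it was 0.0396, and 0.0866 with these clones added as well. Of 26 clones of the 20 named genes 23 were negative, where sides shuffled within blocks gave 18.47 on average. The two-sided permutation p was 0.0215, or 0.215 adjusted over the lists. The wider gene ontology annotation was examined after the results were seen. There, 23 of 34 structural constituents of the ribosome were negative (Fisher's exact test p = 0.0565, adjusted p = 0.942), as were 30 of 53 genes of translation.

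The named genes of the cell cycle list lay mostly on the positive side, 11 of 13, with a median of 0.29, but did not pass the test (camera adjusted p = 0.0685, percentile 89.0). The members with the largest ratios were Smc4, a condensin subunit (0.69 ± 0.44), the histone variant H2az1 (0.49 ± 0.042) and Ccna2, cyclin A2 of S phase and mitosis (0.40 ± 0.13; SD, n = 2). Ccnd1, the G1 cyclin D1, was negative at -0.40 ± 0.10, as was Cks1b. All 13 passed when adjusted over the list alone. Fisher's exact test of positive against negative genes gave an adjusted p of 0.0476. The camera adjusted p was 0.260 with block medians subtracted (median 0.16). With an estimated correlation it was 0.853, the same as for every tested list. Of the 16 clones of these genes 13 were positive, close to the 12.51 that sides shuffled within blocks gave on average (share of shuffles with as many 0.5287). The wider gene ontology annotation, examined after the results were seen, did not show this lean. Of 84 named genes annotated to the cell cycle, 40 were positive and 44 negative (median log2 ratio -0.15). Positive were 16 of 29 genes of mitosis, 23 of 43 of cell division and 13 of 24 of DNA replication.

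RNA splicing and processing is the group to which the known activity of Bclaf1 relates. Its genes lay on both sides, with 10 positive and 7 negative of 17 (median 0.28, mean 0.069, camera adjusted p = 0.804). Luc7l3, a U1 snRNP-associated protein, had 0.33 on array 1 and 2.29 on array 2, Srsf7, a serine/arginine-rich splicing factor, had -0.53 and -1.98, and Rbm39 had 0.59 and 0.97. Thrap3, the closest relative of Bclaf1, had -0.46 ± 0.19 (SD, n = 2) and was named after its value was seen. Adjusted over the list alone, 12 of the 17 passed. Of the 34 apoptosis and p53 response genes only 4 were named, with 0 passing when adjusted over the list alone. Bcl2l1, the anti-apoptotic relative of Bcl2, had -0.54 ± 0.34, Bnip3l -0.24 ± 0.14 and the caspase inhibitor Xiap 0.19 ± 0.035; the clones of the fourth gene, Ccng1, lay on opposite sides, at 0.29 and -0.48.

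Lung developmental signalling genes were 5 positive and 3 negative of 8 (median 0.15, camera adjusted p = 0.819; 6 passed when adjusted over the list alone). Tgfbr1, a TGF-beta receptor, had -0.46 ± 0.11, and the transcriptional inhibitors Id2 and Id3 lay on opposite sides with 0.37 ± 0.049 and -0.36 ± 0.024 (SD, n = 2). Oxidative phosphorylation genes were 1 positive and 5 negative of 6 (median -0.30, camera adjusted p = 0.346; 6 passed when adjusted over the list alone), with Ndufs4 of complex I at -0.50 ± 0.28 and the complex IV subunits Cox6b1 and Cox6a1 at -0.42 ± 0.058 and -0.34 ± 0.015. Hypoxia and glycolysis genes were 1 positive and 4 negative of 5 (median -0.31, camera adjusted p = 0.496; 0 passed when adjusted over the list alone; with clones of conflicting name under their gene ID, 2 positive and 4 negative, adjusted p = 0.801), with Ddit4 at -0.46 ± 0.34, hexokinase Hk1 at -0.42 ± 0.35 and lactate dehydrogenase Ldha at 0.33 ± 0.15. Immediate early and stress genes were 3 positive and 3 negative of 6 (median -0.042, camera adjusted p = 0.819; 0 passed when adjusted over the list alone), with the metallothionein Mt2 at -0.31 ± 0.10, Hspa8 at -0.28 ± 0.029 and Klf4 at 0.23 ± 0.0065.

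Of the structural groups, smooth muscle and myofibroblast genes were 2 positive and 3 negative of 5 (median -0.25, camera adjusted p = 0.819; 5 passed when adjusted over the list alone). Smooth muscle myosin Myh11 lay at 0.63 ± 0.12 and caldesmon Cald1 at 0.36 ± 0.045, against -0.51 ± 0.022 for Myocd, a coactivator of smooth muscle genes. Extracellular matrix and fibroblast genes were 2 positive and 4 negative of 6 (camera adjusted p = 0.804; 5 passed when adjusted over the list alone), with tenascin Tnc at 0.91 ± 0.36, laminin Lamc1 at 0.43 ± 0.12 and fibronectin Fn1 at -0.40 ± 0.011 (SD, n = 2). The median of this list was -0.24 and its mean 0.020, so they differed in sign; camera gave the direction as down. With block medians subtracted, the median moved to -0.15 for this list, 0.13 for splicing, 0.093 for lung developmental signalling and -0.082 for immediate early genes.

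**Figure D3:**
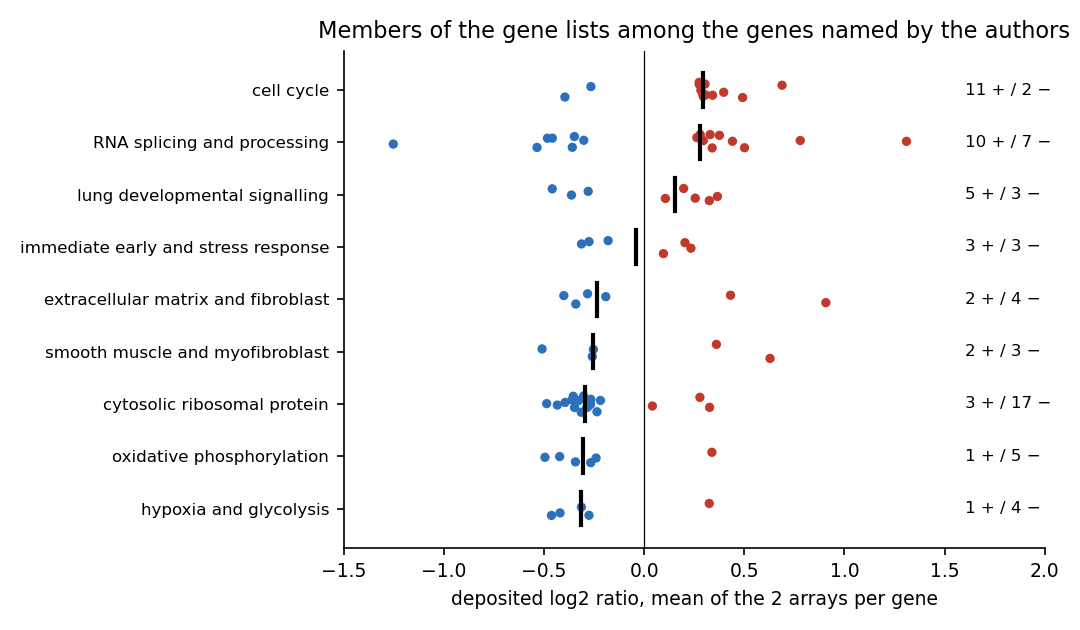
Mean log2 ratio over the arrays of each named gene (points, red positive and blue negative) in the 9 tested gene lists (rows), with the list median as a black bar and the counts of positive and negative genes at the right. Of the cytosolic ribosomal proteins 17 of 20 lie below 0, and of the cell cycle genes 11 of 13 lie above 0.

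Cell type markers were too few for a test and are given as values. Among 20 alveolar type II genes 2 were named, fatty acid synthase Fasn at -0.41 ± 0.036 and Pcyt1a, of surfactant phosphatidylcholine synthesis, whose clones lay at 0.47 and -0.62. Alveolar type I genes were Ahnak (0.69 ± 0.65), Igfbp2 (-0.52 ± 0.068) and Emp2 (-0.43 ± 0.14), and airway genes were Cbr2 (0.37 ± 0.016), Gsta4 (-0.34 ± 0.14) and the ciliary gene Rsph1 (0.24 ± 0.13). The 1 endothelial gene was Eng at -0.38 ± 0.32. With block medians subtracted, Fasn lay at -0.29, Gsta4 at -0.18, Rsph1 at 0.13 and Eng at -0.24. Ahnak, Igfbp2, Emp2 and Cbr2 moved little, to 0.68, -0.50, -0.41 and 0.39. Heart and striated muscle genes went both ways, with Tnnt2 at 0.86 ± 0.56, Mb at 0.54 ± 0.52, Pln at -0.66 ± 0.31 and Myh6 at -0.37 ± 0.26 (SD, n = 2). Adjusted over the list alone, 1 alveolar type II, 2 alveolar type I, 2 airway, 0 endothelial, 0 heart and 3 sex-linked genes passed. None of the 21 red cell, 20 lymphocyte and 22 liver genes was among the named genes, and of the leukocyte genes only Cd53 was named, with a value on 1 array.

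The ratios also differed by where on the array set a clone came from. In blocks of 384 consecutive clone numbers, which matched the printing plates in blocks 1 to 40, blocks 1 to 10 held 520 up-regulated and 130 down-regulated clones of the authors' deposited tables, and blocks 30 to 40 held 82 and 677. Block 35 held 1 up-regulated and 79 down-regulated clones, whereas block 36 went the other way with 41 and 17. The chi-square of block against side was 1143 with 58 degrees of freedom, and the highest of 2000 random shuffles was 109. Of the 10 genes named on the positive side, 7 came from blocks 56 to 59. Among the 218 genes with more than 1 named clone, 110 had clones on both sides. Of their 309 pairs of clones, 53.4% shared a sign, against 50.07% in shuffles (one-sided permutation p = 0.131). The ratios within these pairs had a Pearson r of 0.059, so the value of 1 clone need not hold for other clones of its gene.

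**Figure D4:**
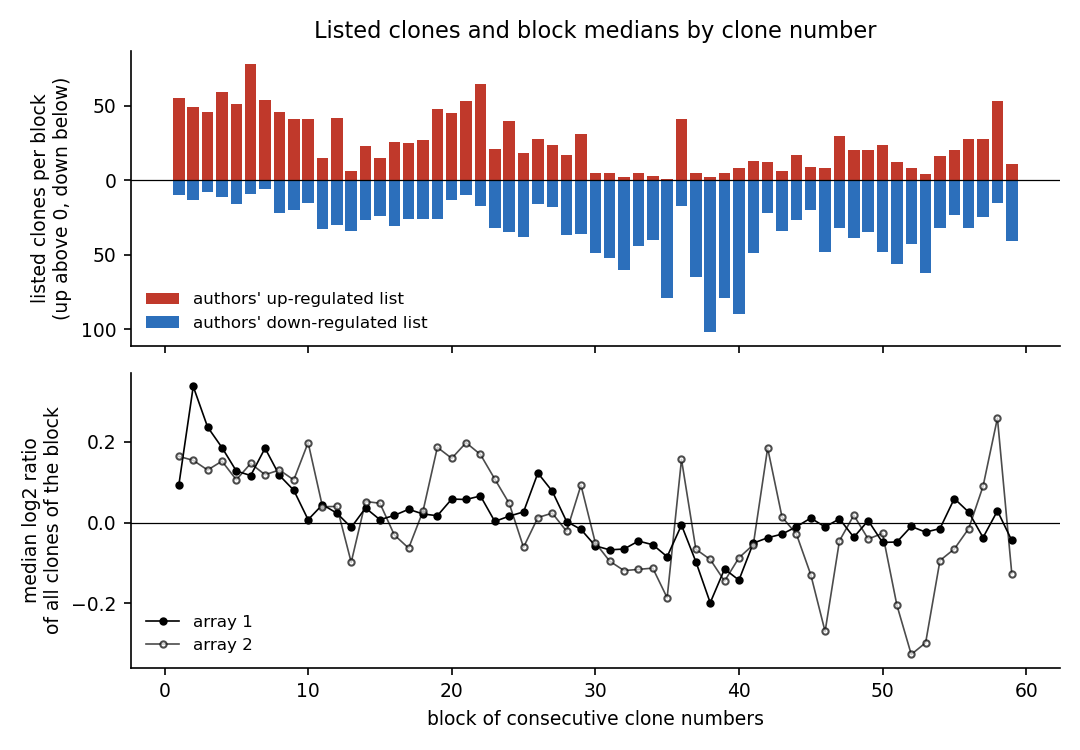
Upper panel, number of clones of the authors' up-regulated list (red, above 0) and down-regulated list (blue, below 0) in each of the 59 blocks of 384 consecutive clone numbers; lower panel, median log2 ratio of all clones of the block on array 1 (filled) and array 2 (open). Blocks 1 to 10 hold mostly up-regulated clones (520 against 130) and blocks 30 to 40 mostly down-regulated ones (677 against 82).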

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

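The subtraction of block medians, Fisher's exact test, the omission of genes whose clones disagree and the naming of conflicting clones by gene ID, alone or after block centring, were chosen after the data were seen. The count of 0 calls at the adjusted threshold held under each of the 9 alternatives that gave a count. At an unadjusted p under 0.05 the count was 1861 with the ordinary test and 1732 of 2253 genes when clones of a gene were averaged, where fewer features were tested. These genes, all selected by the authors, had a lowest adjusted p of 0.0521, and 2096 had one under 0.10. Block centring lowered the positive percent of these clones to 45.0; the cause was not tested.

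Clones past 1.5-fold on both arrays moved most on the negative side, to 113 with equal MAD and 146 after quantile normalization, which brought opposite clones to 54. Past 2-fold, counts were 36 positive, 2 negative and 2 opposite by construction. On single arrays 728 to 1172 clones were positive and 154 to 1049 negative, since 1 array alone then decides. A single array leaves no degrees of freedom and was not tested.

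The ribosomal list kept its direction under every alternative, with adjusted p from 0.00633 to 0.853. It missed the threshold after quantile normalization (median -0.34, adjusted p 0.0618), with an estimated correlation (-0.29, 0.853), with fry (-0.29, 0.105), which asks another question, and with block medians subtracted and conflicting clones under their gene ID (-0.26, 0.0866); the cause was not tested. With conflicting clones under their gene ID the mean over the sex-linked genes fell from 0.37 to 0.052. For cell cycle genes (median 0.29), adjusted p ran from 0.0476 with Fisher's exact test to 0.853 with an estimated correlation. The estimated correlation rests on 1 residual degree of freedom and gave every tested list a camera adjusted p of 0.853. The 7 other tested lists had 0 adjusted p under 0.05 (0.0593 to 1). Block centring moved the medians of cell cycle genes to 0.16, splicing from 0.28 to 0.13, extracellular matrix from -0.24 to -0.15, lung signalling from 0.15 to 0.093 and immediate early genes from -0.042 to -0.082. With every clone a member the last 2 were 0.26 and -0.0033, and immediate early genes lay at -0.18 without genes whose clones disagree. On single arrays medians were -0.26 to -0.20 for smooth muscle, -0.21 to -0.19 for extracellular matrix, 0.20 to 0.28 for splicing and -0.31 to -0.22 for hypoxia.

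For the 23 clones of the 10 genes per side and the Y-linked genes, 206 of 207 values under alternatives had the sign given; Dcaf7 turned to 0.048 when its clones were averaged, because another clone lay on the opposite side. For the 46 named list members, averaged over clones, 275 of 276 values under centring, scaling, quantile normalization, block centring and single arrays did; Pcyt1a, at -0.077, lay at 0.049 on array 1. Of these values 20 moved by more than the SD between arrays, Klf4 to 0.065 after block centring. The 10 genes per side were picked for the same sign on both arrays, and the authors chose all named clones on these arrays. The counts of kept signs were thus largely fixed by selection and do not measure robustness. The filter on dim spots was not run.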

Other observations

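The comparison of gene annotations, the share of same-sign clone pairs, the tests of the sex-linked and abundant genes and the test of clustering by block were chosen after the results were seen.

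Gene ontology annotations in the authors' tables were compared between the sides over 1865 named genes. Of 105 genes annotated to the mitochondrion, 65 were negative and 40 positive (median log2 ratio -0.24), and of 31 genes of ion transport 22 were negative. Genes of the extracellular region went the other way, with 18 of 27 positive (median 0.31). The related annotations did not, with 7 of 23 positive for the extracellular matrix (median -0.28) and 69 of 144 for the extracellular space (median -0.13). Of 106 annotations, 2 had an unadjusted p under 0.05 by Fisher's exact test and 0 an adjusted p under 0.05 (lowest 0.942). With sides shuffled within blocks the two-sided permutation p was 0.026 for the mitochondrion, 1 for ion transport and 0.532 for the extracellular region. Of the 106 annotations 4 had an unadjusted p under 0.05 by these shuffles (lowest adjusted p 0.9535), so no annotation passed either test. On the X chromosome 35 clones were in the up-regulated and 34 in the down-regulated list.

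The side of a listed clone followed its block of clone numbers. If different genes in different blocks were the reason, clones of 1 gene from different blocks should share a sign, but 152 of 292 such pairs did (share 0.5205, one-sided permutation p = 0.268). The difference within these pairs rose with the difference of the block medians. The slope was 1.90, where random swaps gave an SD of 0.259 (one-sided permutation p = 1e-05, the smallest the swaps can give). The authors chose all these clones on the same arrays, and the swaps treat pairs that share clones or blocks as independent. This p may therefore be too small. A location effect may account for part of the split between the authors' lists. Blocks held 7.8% and 12% of the variance of the arrays. How much of the split the location effect accounts for, and whether the location effect arose in printing, hybridisation or normalization, stays open.

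For the sex-linked clones, more female tissue in the channel on the positive side stays open. All 8 values had the sign it needs, but this explanation was set against these 4 clones after their signs were seen. The authors had also selected all 4 clones, so the values are no independent test of this explanation. After subtraction of block medians the mean absolute log2 ratio of these clones was 0.989 of the deposited one, but Xist dominates this mean. Block medians ran from -0.20 to 0.34 on array 1 and from -0.33 to 0.26 on array 2. They were thus too small to give the Xist ratio, at 2.42 before and after. Ddx3y went from -0.87 to -0.86, and the Eif2s3y clones from -0.69 to -0.55 and from -0.19 to -0.30. All 4 clones kept their sign. The labels give no sex, so a difference in sex between the pooled or single lungs, an effect of genotype on Xist and a dye effect stay open, and no test here separates them. A difference in sex would be a second difference between the channels beside the genotype.

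For the ribosomal proteins, block offsets cannot be told apart from a shift of their own, because the outcome depends on the naming of 5 clones and on the adjustment over lists. Of 26 clones 23 were negative, where sides shuffled within blocks gave 18.47 on average and as many in a share of 0.01075 (two-sided permutation p = 0.0215, adjusted over 10 lists 0.215). With the 5 clones under their gene ID the share was 0.0633 (two-sided permutation p = 0.1266, adjusted over 11 lists 0.8745). With block medians subtracted, camera's adjusted p was 0.0396 without and 0.0866 with them, and the median stayed at -0.26 either way. A further set was 19 genes outside the ribosome taken as abundant, 8 of them also in another list. Their abundance was not measured here. Of these genes 14 were negative (share 0.7368) against 51.5% of all named genes (Fisher's exact test p = 0.0648). Canx, counted as negative, lay at -0.0075 with opposite signs on the arrays. Of the 20 clones of the set 14 were negative, where sides shuffled within blocks gave 10.66 on average and as many in a share of 0.0388. The set also holds the elongation factor genes Eef1a1 and Eef1g, at -0.54 and -0.25, so it is not clear of the translation machinery. A shift of abundant transcripts as a whole was thus neither excluded nor established. An effect of the genotype stays open and was not tested apart from the dye.

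For the genes of the cell cycle list, the same shuffles gave as many positive clones with a share of 0.5287 (13 of 16, 12.51 on average), so block offsets alone may give this excess. The side of named clones differed between the 21 chromosomes with a permutation p of 0.0421, which does not account for blocks. Of the 36 clones past 2-fold on both arrays on the positive side, 9 came from block 58 (permutation p of the most clones in 1 block = 5e-05, the smallest the 20000 placements can give). Blocks 56 to 58 together held 19, a range picked after it was seen and not tested.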
